A study of Homo sapiens with 18 samples.

How the data were processed

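RNA of BCi-NS1.1 cells grown at an air-liquid interface was sequenced in 18 libraries, 3 for each of 6 groups: untreated and HO53-treated cultures at 3 times. Libraries were made with the Illumina TruSeq RNA v2 kit, with poly-A selection and random hexamer priming per the labels' protocols, and strand-specific preparation is not stated, so reads of a gene and of an overlapping gene on the other strand cannot be told apart. The authors quantified transcripts with kallisto 0.45.0 against GRCh38 and used sleuth 0.30, per the submitters' processing notes. The deposited tables hold estimated counts per transcript, which are not normalized and need not be whole numbers, with the TPM and effective length of each transcript per the file headers. A second table per sample held the same values within a relative difference of 5e-06 and was used only as an alternative.

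The 228297 transcripts of each table were matched by Ensembl identifier to GENCODE 29, the annotation given with the reference genome, which also supplied symbols, biotypes and coordinates. Of these, 205336 (89.9%) matched, carrying between 96.8% and 97.27% of the counts of a library, and the estimated counts were summed to 57638 genes and rounded to whole numbers. The 22961 unmatched transcripts, which include sequences of alternative haplotypes, were left out of the comparisons. Single genes such as MUC5AC and FLOT1 that have copies there are uncertain. Genes with at least 25% of their exonic bases in exons of other genes (35 of 644 checked) are marked as uncertain where named, and so are families of near-identical genes. Because kallisto divides reads among similar transcripts by estimation, such members share their error.

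Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 27751 genes. Counts were scaled with TMM factors and fitted with edgeR 4.0.16's quasi-likelihood model in R 4.3.3, in one fit of all 18 libraries with a mean for each of the 6 groups and 12 residual degrees of freedom. The contrasts were HO53 against control at each time, the 3 differences of that effect between times, and 24 h against 4 h in the controls. P-values were adjusted by Benjamini-Hochberg and called under 0.05, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.073. A gene was counted in the same direction at all 3 times when each time called it that way. The deepest and shallowest libraries differed by less than 1.5 times in depth, and CPM values carry the SD of 3 libraries.

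The contrasts, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 35 lists: core autophagy, autophagy receptors, lysosome, AMPK, mTORC1 and TFEB regulators, histone deacetylases and acetyltransferases, genes raised by deacetylase inhibitors, antimicrobial genes, ciliated, club and goblet, basal and squamous genes, rare airway cell markers, membrane-bound mucins, non-epithelial markers, junctions, NF-kB targets, interferon, ATF4 and p53 targets, the unfolded protein response with its endoplasmic reticulum chaperones, NRF2 targets, cell cycle, cholesterol synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, neuronal genes, metallothioneins, ribosomal proteins, clock, heat shock, aryl hydrocarbon receptor targets, immediate early and mesenchymal genes. They were tested with camera of limma 3.58.1 (preset correlation 0.01, at least 5 tested members), with camera at an estimated correlation and with fry, and adjusted over 105 tests. Members not tested because the counts of their matched transcripts were low were DEFB103A, TSPAN8, LORICRIN, CRNN, ATP6V1G3, ASCL1, CALCA, GRP, PTPRC, TYROBP, NDUFA6, NEFM, SYT4, MT1H, HSPA1A and IER3. List medians were also ranked among 10000 random lists matched on mean expression in 100 bins.

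Named genes were, per time, the 6 protein-coding genes with the largest rise and the 6 with the largest fall among called genes with a mean CPM over all 18 libraries of at least 5 and all HO53 values outside the control range. For each called list, and for the autophagy, lysosome, antimicrobial, deacetylase inhibitor, junction and airway lists at every time, up to 2 rising and 2 falling called members by smallest p with a mean CPM of at least 1 were added. For each difference between times the 3 largest each way were added, and CAMP, DEFB1, TFEB, MAP1LC3B, SQSTM1, ULK1, H1F0, CDKN1A, FOXJ1, MUC5AC and KRT5 were always reported. A gene at 0 in all controls is given against a floor of 3 counts per library.

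The fit was tested on simulated counts for HO53 against control at 4 h over 27751 genes. It recovered 26%, 46%, 72% and 92% of 50 genes each changed 1.25-, 1.5-, 2- and 4-fold, among 230 changed genes that also held a list of genes shifted 1.5-fold, with 4.96% false among 141 calls and 0 calls at the unchanged 8 h. All simulated groups started from the means of the 4 h controls. The data called 16841 genes at 4 h, so the simulation does not test TMM scaling where most genes change. Alternatives were median-of-ratios and upper-quartile scaling, no filter and a stricter filter (5 CPM in 3 libraries, with the scaling recomputed), DESeq2 1.42.0, limma-voom, the second table of each sample, ranked camera, transcript length offsets, fits of only the times compared, the replicate number as a block, and leaving out each library in turn. Total-count scaling, the list tests under other scalings and the stricter filter, and camera on the difference between 24 h and 4 h were added after the data were seen. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.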

Results

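The series measured the transcriptome of BCi-NS1.1, an established human bronchial epithelial cell line, after 26 days at an air-liquid interface, a culture form in which the cells differentiate on a porous membrane with medium below and air above. The stated purpose was to evaluate how HO53, a small molecule known here only by its code name, affects the induction of autophagy. HO53 was added to the lower chamber at 75 µM, and RNA of treated and of untreated cultures was sequenced at 4 h, at 8 h and at 24 h. Each of the 6 groups had 3 libraries, 18 in all, made from poly-A RNA. The labels name triplicates without saying whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The untreated cells served as the background for every value below, and no vehicle is named for them.

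Each library held between 80058844 and 105212330 estimated counts summed over genes. Libraries of one group correlated at a Pearson r of at least 0.9907 on the log2 CPM scale, taken across genes, which are not independent replicates. The counts of every replicate pair differed by more than sampling noise (chi-square per degree of freedom between 7.1 and 28.3), so no library was a copy of another. With at least 5 counts as the minimum, the controls detected between 25824 and 27572 genes and the HO53 libraries between 28196 and 30865. At 8 h, mitochondrial genes took between 10.54% and 11.17% of the counts with HO53 and between 8.87% and 9.6% in the controls. At 24 h the order was the reverse, between 9.56% and 10.14% with HO53 and between 10.21% and 10.53% in the controls, and at 4 h the groups overlapped. After filtering, 27751 genes were tested. The first principal component held 58.5% of the variance and separated all 9 HO53 libraries from all 9 controls, and the second held 18% and set the 24 h HO53 libraries apart from those of 4 h and 8 h.

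**Figure D1:**
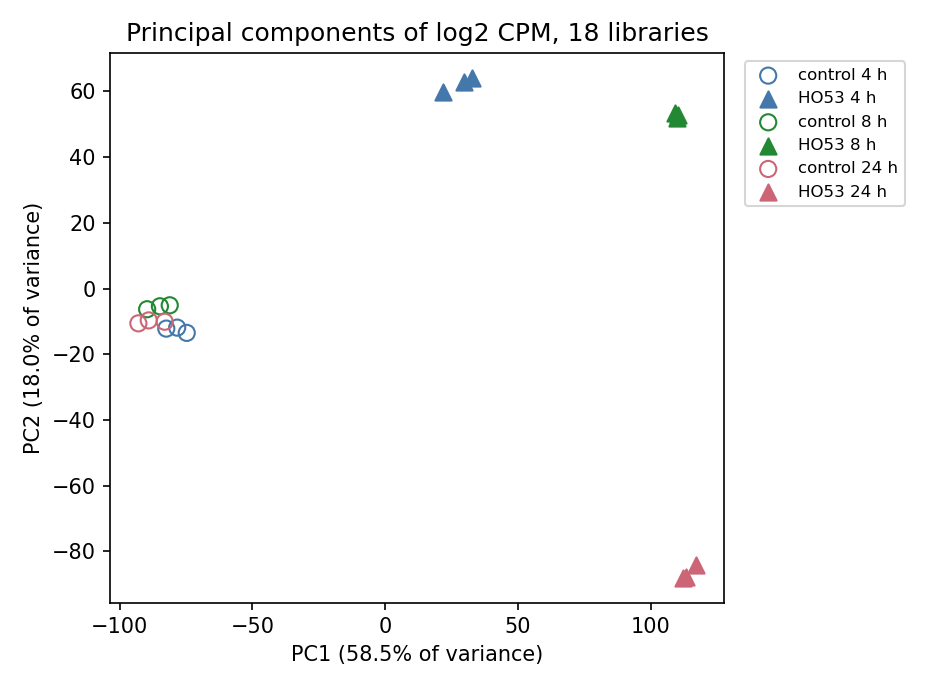
Principal component scores of the 18 libraries from log2 CPM, with PC1 (58.5% of variance) on the x axis and PC2 (18% of variance) on the y axis, open circles for controls and filled triangles for HO53 libraries, coloured by time. The 9 controls sit together, and the 9 HO53 libraries fall into 3 sets of 3 by time.

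The following directions are relative to TMM scaling, under which the median log2 fold change of all tested genes was 0.13 at 4 h, 0.22 at 8 h and 0.14 at 24 h. Upper-quartile scaling moved this median up by 0.30, 0.40 and 0.28, total-count scaling moved it up by 0.15 at 24 h, and median-of-ratios scaling moved it by -0.11 at 8 h. For the differences between times, upper-quartile scaling moved it by 0.10 for 8 h against 4 h and by -0.12 for 24 h against 8 h, and total-count scaling by 0.19 for 24 h against 4 h and by 0.23 for 24 h against 8 h. A stricter expression filter left 12856 genes and recomputed the scaling on them. It moved their log2 fold changes up by a median of 0.21, 0.32 and 0.27 at 4 h, 8 h and 24 h. Some list medians are also given relative to all genes. Scaling moves this value little, but it depends on the genes tested. Direction flips under another scaling are marked.

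The series asked about autophagy, but only mRNA was measured, not proteins or the process. Most core autophagy genes, whose products build the autophagosome from initiation to LC3 conjugation, were lower with HO53 at 4 h and 8 h. The list did not pass with an estimated correlation. Of the 34 core genes, 27 fell and 4 rose at 4 h, 29 fell and 5 rose at 8 h, and 23 fell and 4 rose at 24 h, and the counts adjusted over the list alone were the same. Under upper-quartile scaling 19 fell and 10 rose at 4 h, 22 fell and 9 rose at 8 h, and 12 fell and 11 rose at 24 h. MAP1LC3B, which encodes the LC3B protein of autophagosome membranes, fell 1.35-fold at 4 h and 1.65-fold at 8 h, from 72.2 ± 3.2 CPM to 43.8 ± 1.9 CPM (SD, n = 3). Its relative MAP1LC3A did the opposite and rose 1.40-fold at 8 h and 3.98-fold at 24 h, from 9.1 ± 0.35 CPM to 36.3 ± 2.2 CPM (SD, n = 3; log2 fold change 1.99 ± 0.06 (SE), edgeR adjusted p = 8.19e-17).

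The list median was -0.46 at 4 h, -0.74 at 8 h and -0.28 at 24 h on the log2 scale, or -0.60, -0.96 and -0.42 relative to all genes. Limma's camera called the fall at 4 h (adjusted p = 7.99e-06), 8 h (2.91e-07) and 24 h (0.017). These calls did not hold (adjusted p = 0.446, 0.433 and 0.788 with an estimated correlation). At 24 h the list median was 0.00 under upper-quartile scaling, where camera gave an adjusted p of 0.159, and total-count scaling gave 0.0529. The stricter filter kept the call at 8 h (adjusted p = 0.0135), not at 4 h (0.0563, median -0.25) or 24 h (0.577, median -0.01). Among 10000 random lists matched on expression, the median ranked at percentile 0.68 at 4 h, 0.83 at 8 h and 72.5 at 24 h. Those lists had medians of -0.24, -0.38 and -0.36, so at 24 h the list lay within the fall of similarly expressed genes.

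Single core genes differed in their time course. ATG14, a subunit of the lipid kinase complex that starts autophagosome formation, fell 2.66-fold at 8 h (log2 fold change -1.41 ± 0.04 (SE), edgeR adjusted p = 1.86e-16) and 2.68-fold at 24 h. PIK3C3, the catalytic subunit of that complex, fell 2.35-fold at 8 h. ATG3 and ATG101, the first an enzyme of LC3 conjugation and the second a subunit of the ULK1 complex, fell 1.82-fold and 1.99-fold at 4 h. ATG10, another conjugation enzyme, rose 1.17-fold at 4 h (edgeR adjusted p = 0.013), a call lost without the expression filter (0.0599), with DESeq2 (0.0595), with transcript length offsets (0.115) and without the third HO53 library (0.0742). ULK1, the kinase that initiates autophagy, fell 1.52-fold at 4 h. Its log2 fold change at 8 h was -0.32 ± 0.06 (SE), a direction that flipped under upper-quartile scaling (0.08), and the call was lost under the stricter filter (-0.01, edgeR adjusted p = 0.892). At 24 h ULK1 did not pass (-0.10, edgeR adjusted p = 0.124), with flipped values of 0.18 under upper-quartile scaling (edgeR adjusted p = 0.00367), 0.17 under the stricter filter and 0.05 under total-count scaling. It passed as lower at -0.15 with median-of-ratios scaling (edgeR adjusted p = 0.044) with DESeq2 (0.0379) and without the third control (edgeR adjusted p = 0.0484). VMP1, a membrane protein needed for autophagosome formation, rose 1.38-fold at 4 h and 1.34-fold at 8 h. GABARAP, an LC3 relative, fell 2.18-fold at 24 h, although 55.7% of its exonic bases lie in exons of other genes and its count is uncertain. ATG4B, a protease that processes LC3, rose 1.39-fold at 24 h. MAP1LC3B was 1.15-fold lower at 24 h (log2 fold change -0.20 ± 0.06 (SE), edgeR adjusted p = 0.00641), and this direction flipped under upper-quartile scaling (0.09) and under the stricter filter (0.07), and the call was lost under total-count scaling (-0.05, edgeR adjusted p = 0.414).

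**Figure D2:**
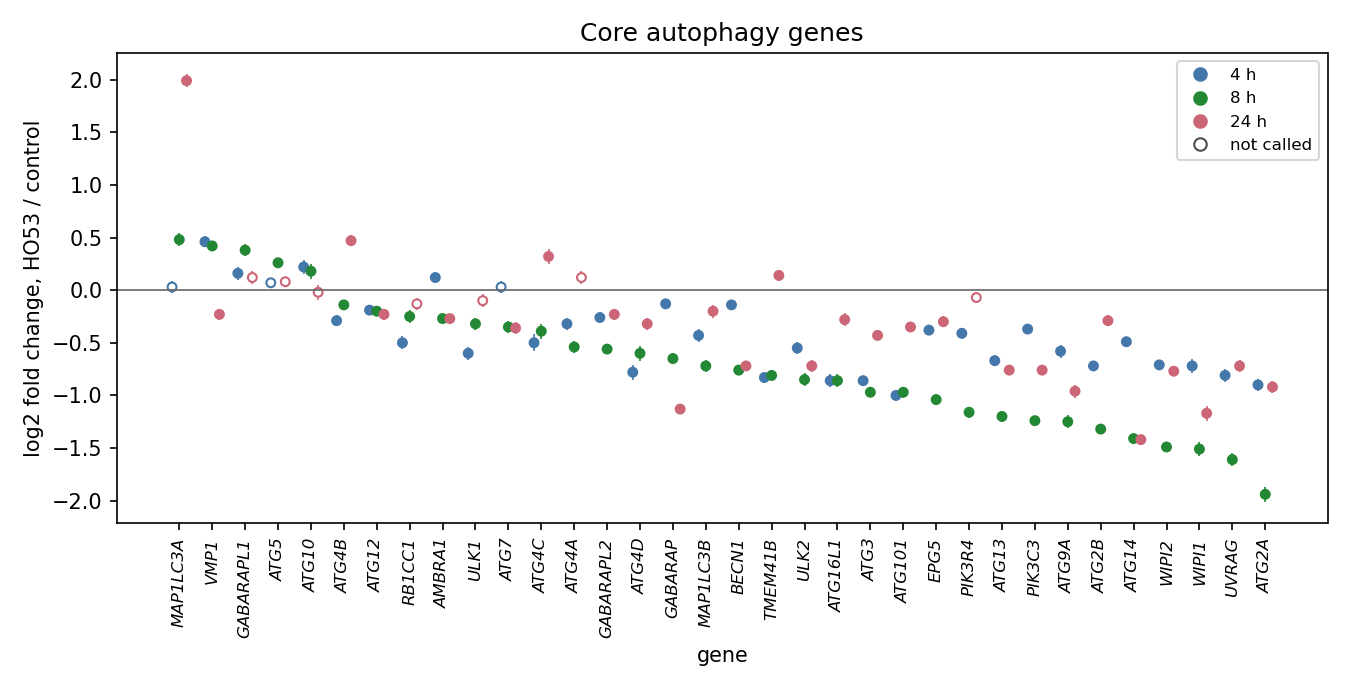
Log2 fold change of HO53 over control (y axis) for each of the 34 core autophagy genes (x axis, ordered by the value at 8 h), coloured by time, with bars for the standard error, filled points where the edgeR test was passed and open points where it was not. At 8 h 29 genes fell and 5 rose under TMM scaling, while under upper-quartile scaling 22 fell and 9 rose.

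Receptors of selective autophagy moved both ways. Of 18 receptors, 2 rose and 8 fell at 4 h, 5 rose and 10 fell at 8 h, and 4 rose and 10 fell at 24 h, the same counts as adjusted over the list alone. The list did not pass limma's camera test at any time (adjusted p = 0.491, 0.356 and 0.354), and its medians of -0.09, -0.24 and -0.27 flipped to 0.22, 0.17 and 0.02 under upper-quartile scaling, where 12, 11 and 9 rose and 3, 5 and 8 fell. SQSTM1, which encodes the p62 receptor, fell 1.23-fold at 4 h, 1.42-fold at 8 h and 1.46-fold at 24 h, from 325 ± 17 CPM to 222 ± 9.2 CPM (SD, n = 3), and its direction at 4 h flipped under upper-quartile scaling (log2 fold change 0.01), with the call lost under the stricter filter (edgeR adjusted p = 0.0601). NBR1 fell 2.26-fold at 8 h and 2.57-fold at 24 h, and TAX1BP1 fell 1.40-fold, 1.73-fold and 1.89-fold. TOLLIP fell 1.41-fold at 4 h. In contrast RETREG1, a receptor for turnover of the endoplasmic reticulum, rose 2.57-fold, 4.44-fold and 5.43-fold (log2 fold change at 24 h 2.44 ± 0.07 (SE), edgeR adjusted p = 8.9e-17), and RTN3, another such receptor, rose 1.31-fold, 1.30-fold and 1.81-fold.

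Lysosomal genes moved both ways. Of 36 genes of this list, 6 rose and 12 fell at 4 h, 9 rose and 24 fell at 8 h, and 8 rose and 25 fell at 24 h, as they did adjusted over the list alone. Under upper-quartile scaling 26, 19 and 12 rose and 6, 13 and 19 fell. Limma's camera called the fall at 8 h (adjusted p = 0.0172; adjusted p = 0.818 with an estimated correlation) and 24 h (adjusted p = 0.00341; adjusted p = 0.745 with an estimated correlation) and not at 4 h (adjusted p = 0.307). The medians were -0.03 (flipped to 0.28 under upper-quartile scaling), -0.29 and -0.45, or -0.16, -0.51 and -0.59 relative to all genes. The median at 8 h flipped to 0.12 under upper-quartile scaling and to 0.03 under the stricter filter, and neither call held under upper-quartile scaling (adjusted p = 0.504 and 0.0529) or the stricter filter (adjusted p = 0.743 and 0.394). Against expression-matched random lists the medians ranked at percentiles 23.4 at 8 h and 8.43 at 24 h. MCOLN1, the lysosomal calcium channel, fell 3.88-fold at 8 h, the proton pump subunit ATP6V1C1 fell 1.94-fold at 4 h and 2.94-fold at 8 h, PIP4P1 fell 1.92-fold at 4 h. At 24 h the hydrolase genes GBA and HEXA fell 3.53-fold and 2.68-fold, the first an uncertain value because GBA has a near-identical pseudogene. PSAP, the precursor of the saposins, rose 1.35-fold, 1.91-fold and 2.39-fold, the pump subunit ATP6V1B2 rose 1.69-fold at 8 h and 2.39-fold at 24 h, and CTSZ, a cathepsin, rose 1.27-fold at 4 h.

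TFEB, the transcription factor of lysosomal and autophagy genes, fell 1.82-fold at 24 h, from 54.8 ± 1.5 CPM to 30.2 ± 1.4 CPM (SD, n = 3; log2 fold change -0.86 ± 0.04 (SE), edgeR adjusted p = 3.39e-13). At 8 h it was 1.09-fold lower (-0.13 ± 0.04 (SE), edgeR adjusted p = 0.0136), which flipped to 0.28 under upper-quartile scaling and to 0.19 under the stricter filter, where it passed as higher. The call at 8 h was lost without the first HO53 library of 8 h (edgeR adjusted p = 0.0744) and with transcript length offsets (0.272). At 4 h it was 1.08-fold higher (edgeR adjusted p = 0.0402), a call lost under median-of-ratios (0.284) and total-count scaling (0.152), with DESeq2 (0.332), with the replicate block within each time (0.0537), without the expression filter (0.212) and without the first or second library of either group (edgeR adjusted p between 0.102 and 0.217). In the list of 28 regulators of AMPK, mTORC1 and TFEB, 11 rose and 14 fell at 4 h, 9 rose and 15 fell at 8 h (17 adjusted over the list alone), and 5 rose and 19 fell at 24 h. Camera called the fall of this list at 24 h (limma adjusted p = 0.0399, adjusted p = 0.704 with an estimated correlation). The median at 24 h ranked at percentile 51.25 among expression-matched random lists, so the fall was that of genes expressed at a similar level. The camera call was lost under upper-quartile (0.281) and total-count scaling (0.12), under the stricter filter (0.701) and without replicate 2 (0.059). At 4 h and 8 h the list was not called (0.493 and 0.148), with medians of -0.15 and -0.24 that flipped to 0.16 and 0.17 under upper-quartile scaling. There 16, 14 and 11 of its genes rose and 5, 9 and 13 fell at the 3 times. PRKAA2, a catalytic subunit of AMPK, rose 18.1-fold at 24 h (log2 fold change 4.18 ± 0.13 (SE), edgeR adjusted p = 1.85e-16), FNIP2 rose 1.43-fold, and MITF and CAMKK2 fell 2.40-fold and 2.63-fold.

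After 4 h of HO53, genes known to be raised by histone deacetylase inhibitors, immediate early genes, squamous and basal cell genes and antimicrobial genes were mostly higher than in untreated cells. Limma's camera called each of these lists, and none of the calls held with an estimated correlation (adjusted p between 0.269 and 0.56 with an estimated correlation). H1F0, the linker histone of differentiated cells, rose 5.44-fold from 265 ± 8.8 CPM to 1440 ± 260 CPM (SD, n = 3; log2 fold change 2.44 ± 0.10 (SE), edgeR adjusted p = 3.82e-14). HMOX1, the heme-degrading enzyme, rose 6.52-fold, and the transcription factor genes JUN and FOS rose 3.48-fold and 3.76-fold. Histone deacetylase and acetyltransferase genes, genes of the unfolded protein response and the mixed list of replication and mitosis genes were called lower as lists, again not with an estimated correlation (adjusted p between 0.433 and 0.651 with an estimated correlation), with EP300, an acetyltransferase, down 2.11-fold and MCM6, a subunit of the replicative helicase, down 3.52-fold.

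In all, 16841 of 27751 genes passed the edgeR test at 4 h, 9103 higher and 7738 lower, and 3934 were at least 2-fold higher and 1323 at least 2-fold lower. Under upper-quartile scaling the split was 14112 higher and 4591 lower. The 6 largest rises among the protein-coding genes named by rule were in TMC8 (10.2-fold), KIAA0408 (9.50-fold), INA (9.21-fold), ANKRD34A (7.86-fold), PLIN2 (7.10-fold), which coats lipid droplets, and IQCN (7.01-fold). For KIAA0408, 82.6% of its exonic bases lie in exons of other genes, so its count is uncertain. The 6 largest falls were in ZNF813 (6.99-fold), SAP130 (4.75-fold), AMER1 (4.70-fold), INCENP (4.6-fold), a mitotic protein, ZNF92 (4.53-fold) and TBC1D12 (4.41-fold), with edgeR adjusted p between 1.37e-15 and 3.3e-14. Zinc finger genes such as ZNF813 and ZNF92 belong to a large family of similar genes, so their counts are uncertain.

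Of 16 genes on the list raised by histone deacetylase inhibitors, 13 rose and 1 fell at 4 h (limma camera adjusted p = 1.94e-05; adjusted p = 0.269 with an estimated correlation). GLRX, a glutaredoxin, rose 2.34-fold and CDKN1A, the cell cycle inhibitor p21, rose 1.53-fold, while CDKN1C, another inhibitor of the cycle, fell 2.13-fold. Of 14 immediate early genes, 11 rose (camera adjusted p = 9.11e-06; adjusted p = 0.433 with an estimated correlation). Among 16 basal cell markers 14 rose and 1 fell (15 rose adjusted over the list alone; camera adjusted p = 0.000408; adjusted p = 0.433 with an estimated correlation), with TP63 up 2.02-fold, KRT15 up 1.83-fold and DLK2 down 1.78-fold. KRT5, the main basal keratin, rose 1.47-fold from 2780 ± 170 CPM to 4090 ± 160 CPM (SD, n = 3). Of 16 squamous genes 13 rose (camera adjusted p = 0.00083; adjusted p = 0.433 with an estimated correlation), among them IVL, a cornified envelope protein, 2.06-fold and TGM1, which cross-links that envelope, 1.61-fold. Of 15 mesenchymal genes 11 rose and 1 fell (camera adjusted p = 0.0101; adjusted p = 0.704 with an estimated correlation; 11 and 2 adjusted over the list alone), with SNAI1 up 2.41-fold, SNAI2 up 1.47-fold and TWIST1 down 1.36-fold, a fall that did not pass under upper-quartile scaling (edgeR adjusted p = 0.0729).

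The antimicrobial list held 18 tested genes, of which 12 rose and 1 fell at 4 h (15 and 1 adjusted over the list alone; camera adjusted p = 0.0153; adjusted p = 0.56 with an estimated correlation). PGLYRP4, a peptidoglycan-binding protein, rose 4.15-fold, S100A8, a subunit of calprotectin, rose 3.13-fold and DEFB1, beta-defensin 1, rose 1.47-fold. ADM was 1.14-fold lower, a direction that flipped under upper-quartile scaling (log2 fold change 0.11) and the stricter filter (0.02). CAMP, which encodes cathelicidin, had 0 counts in every control at 4 h and between 2 and 3 counts per HO53 library, at or under a floor of 3 counts, so no fold is given. With CAMP at its bound the list median at 4 h was 0.66 instead of the fitted 0.68. Of 15 NRF2 target genes 10 rose and 1 fell (camera adjusted p = 0.00241; adjusted p = 0.498 with an estimated correlation), with ABCC2 up 3.40-fold beside HMOX1 and OSGIN1 down 2.77-fold. Of 7 membrane-bound mucins 5 rose (camera adjusted p = 0.00881; adjusted p = 0.433 with an estimated correlation), with MUC15 up 2.62-fold and MUC21 up 2.02-fold. Of 19 glycolysis genes 10 rose and 3 fell (camera adjusted p = 0.0206; adjusted p = 0.813 with an estimated correlation), with ENO2 up 5.99-fold and the glucose transporter SLC2A1 up 1.81-fold. LDHA, a lactate dehydrogenase subunit, was 1.27-fold lower, a call lost under upper-quartile scaling (log2 fold change -0.04, edgeR adjusted p = 0.542). PFKL was 1.22-fold lower, a direction that flipped under upper-quartile scaling (log2 fold change 0.02) and a call lost under the stricter filter (edgeR adjusted p = 0.241). In the same libraries, of 14 markers of fibroblasts, endothelium and immune cells 10 rose (11 adjusted over the list alone; camera adjusted p = 0.0103; adjusted p = 0.498 with an estimated correlation), with VWF up 5.08-fold from 0.921 ± 0.069 CPM to 4.69 ± 0.23 CPM and PECAM1 up 2.25-fold.

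Among the lists that fell at 4 h, 19 of 26 histone deacetylase and acetyltransferase genes fell and 3 rose (camera adjusted p = 6.32e-05; adjusted p = 0.433 with an estimated correlation; 19 and 4 adjusted over the list alone; median -0.44, or -0.57 relative to all genes). KAT6B fell 2.02-fold, and HDAC7 and SIRT5 rose 1.30-fold and 1.27-fold. Of 15 genes of the unfolded protein response, among them endoplasmic reticulum chaperones and degradation factors, 12 fell and 1 rose (camera adjusted p = 0.00518; adjusted p = 0.651 with an estimated correlation; 13 and 1 adjusted over the list alone), with DNAJB9 down 1.95-fold and SEL1L down 1.65-fold. HSPA5 rose 1.18-fold, a call lost without the second control (edgeR adjusted p = 0.0551) or the second HO53 library (0.0506). Of 25 replication and mitosis genes 13 fell and 4 rose (camera adjusted p = 0.00582; adjusted p = 0.53 with an estimated correlation; 14 and 4 adjusted over the list alone), with the helicase subunit MCM3 down 2.24-fold and TK1, a thymidine kinase, and CDK1 up 2.17-fold and 1.54-fold. Of 16 circadian clock genes 9 fell and 6 rose (camera adjusted p = 0.00872; adjusted p = 0.498 with an estimated correlation; 9 and 7 adjusted over the list alone), with TEF down 3.37-fold, CRY2 down 2.48-fold, ARNTL up 1.57-fold and CLOCK up 1.37-fold. Of 27 oxidative phosphorylation genes 15 fell and 0 rose (camera adjusted p = 0.0301; adjusted p = 0.82 with an estimated correlation), with CYC1 down 1.83-fold and UQCRFS1 down 1.45-fold. The median of this list, -0.20, flipped to 0.11 under upper-quartile scaling and to 0.02 under the stricter filter, where the call was lost (0.722 and 0.77). Under upper-quartile scaling 6 oxidative phosphorylation genes fell and 15 rose, against 14 and 10 deacetylase and acetyltransferase genes, 7 and 3 unfolded protein response genes and 11 and 8 replication and mitosis genes. The stricter filter also ended the camera calls of the deacetylase (0.0969, median -0.22), unfolded protein response (0.275, -0.13), clock (0.394, -0.21) and cell cycle lists (0.0868, -0.40 against -0.32 with the usual filter) at 4 h. It ended those of 3 rising lists whose medians were larger under it, membrane mucins (0.0519, 0.97 against 0.50), antimicrobial genes (0.065, 0.89 against 0.68) and non-epithelial markers (0.0563, 0.87 against 0.62). The oxidative phosphorylation median at 4 h ranked at percentile 52.6 among expression-matched lists.

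Airway cell type markers and junction genes at 4 h went as follows. Of 21 ciliated cell markers 12 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.141), with FOXJ1, the master regulator of motile cilia, up 1.82-fold from 20.6 ± 5.3 CPM to 37.4 ± 9.1 CPM (SD, n = 3; edgeR adjusted p = 0.000799), RFX3 up 1.98-fold and MCIDAS down 1.42-fold. DNAH5 rose 1.33-fold, a call lost with transcript length offsets (edgeR adjusted p = 0.0946). MYB fell 1.35-fold, a call lost under upper-quartile scaling (0.488), under the stricter filter (0.207) and without the third control (0.111) or the first (0.0581) or second HO53 library (edgeR adjusted p = 0.0774). Of 16 club and goblet cell markers 6 rose and 3 fell (camera adjusted p = 0.491), with AGR2 up 1.61-fold, FCGBP up 2.31-fold, CYP2F1 down 1.54-fold and CREB3L1 down 1.48-fold. MUC5AC, the main gel-forming mucin of goblet cells, rose 1.38-fold (edgeR adjusted p = 0.00179), a value that is uncertain because part of its transcripts in the tables lie on alternative-haplotype sequences. Of 10 ionocyte, neuroendocrine and tuft cell markers 4 rose and 1 fell (camera adjusted p = 0.252), with POU2F3, a tuft cell factor, up 3.48-fold. LRMP was 1.27-fold lower, a call lost under upper-quartile scaling (edgeR adjusted p = 0.63) and the stricter filter (0.051). ATP6V0D2, a proton pump subunit, was 1.19-fold higher (edgeR adjusted p = 0.0233). Its call was lost under median-of-ratios (0.0615) and total-count scaling (0.0549), without the filter (0.127), with DESeq2 (0.137), length offsets (0.251) or only the times compared (0.0719), and without control 1 (0.0591), control 3 (0.107) or HO53 library 2 (0.115). Of 19 junction genes 9 rose and 4 fell (camera adjusted p = 0.306), with CLDN3 up 1.86-fold, TJP3 up 1.48-fold, MARVELD3 down 2.12-fold and MARVELD2 down 1.56-fold. Neuronal genes (9 of 14 rose, camera adjusted p = 0.144) and metallothioneins (5 of 6 rose, 0.0543) did not pass at 4 h.

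After 8 h, single genes of these groups stood far from the controls. H1F0 stood 7.90-fold above the controls (2000 ± 95 against 253 ± 22 CPM, SD, n = 3), HMOX1 15.1-fold, and DEFB1 7-fold, at 12.3 ± 0.70 CPM against 1.76 ± 0.16 CPM. CDKN1A rose 3.82-fold while the helicase gene MCM6 fell 30.1-fold, from 19.7 ± 0.80 CPM to 0.657 ± 0.057 CPM (SD, n = 3; log2 fold change -4.91 ± 0.09 (SE), edgeR adjusted p = 3.09e-19). Neuronal genes, many of them silenced by REST outside neurons, and metallothioneins, small metal-binding proteins, passed as lists at 8 h, but not with an estimated correlation (adjusted p = 0.114 and 0.269 with an estimated correlation). SYN1, a synaptic vesicle protein, rose 16.8-fold. Heat shock genes and oxidative phosphorylation genes were called lower as lists, and not with an estimated correlation (adjusted p = 0.433 and 0.56 with an estimated correlation).

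The edgeR test called 20090 genes at 8 h, 11322 higher and 8768 lower, of which 6796 were at least 2-fold higher and 3176 at least 2-fold lower, and upper-quartile scaling gave 15869 higher and 5871 lower. By the rule for named genes the largest rises were in INA (92.8-fold), an intermediate filament protein of neurons, PADI3 (92.1-fold), a peptidylarginine deiminase of epidermis, CEND1 (53.3-fold), SYT11 (52.8-fold), HSD11B1 (32.6-fold), which activates cortisone, and RASD2 (29.3-fold). By that rule the largest falls were in MCM6, MCM5 (16-fold), the condensin subunit SMC2 (15.7-fold), the uracil-DNA glycosylase UNG (14.5-fold), the kinetochore protein DSN1 (14.0-fold) and SAP130 (12.9-fold).

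All 6 metallothioneins rose at 8 h (camera adjusted p = 0.00401; adjusted p = 0.269 with an estimated correlation), with MT1E up 4.29-fold and MT2A up 2.32-fold, although the reads of these near-identical genes can be split between them and single values are uncertain. Of the deacetylase inhibitor list 12 of 16 rose and 0 fell (camera adjusted p = 2.91e-07; adjusted p = 0.223 with an estimated correlation), with CPA4 up 8.49-fold. Of 14 neuronal genes 13 rose (camera adjusted p = 0.00241; adjusted p = 0.114 with an estimated correlation), among them TUBB3, neuronal tubulin, 3.46-fold. For TUBB3, 35.8% of the exonic bases lie in exons of another gene. Of the immediate early genes 13 of 14 rose (camera adjusted p = 6.32e-05; adjusted p = 0.433 with an estimated correlation), with FOS up 6.09-fold and JUN up 3.67-fold. Of the mesenchymal genes 14 of 15 rose (camera adjusted p = 0.00505; adjusted p = 0.651 with an estimated correlation), with SNAI1 up 12.4-fold and SERPINE1 up 3.54-fold. The counts in these lists were the same adjusted over the list alone.

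The next lists were also called higher at 8 h with the preset correlation only. Of the antimicrobial genes 13 of 18 rose and 0 fell (camera adjusted p = 0.00154; adjusted p = 0.433 with an estimated correlation), with PGLYRP4 up 9.49-fold. CAMP again had 0 counts in the controls and between 2 and 8 per HO53 library, so no fold is given. With CAMP held at its bound the list median was 1.05 instead of the fitted 1.46. Of the membrane-bound mucins 6 of 7 rose (camera adjusted p = 0.00196; adjusted p = 0.269 with an estimated correlation), with MUC4 up 7.51-fold and MUC15 up 5.90-fold. Of the squamous genes 15 of 16 rose (camera adjusted p = 0.00083; adjusted p = 0.433 with an estimated correlation), with the stress keratin KRT6B up 11.2-fold, an uncertain value because of its close relatives, and IVL up 2.74-fold. Of the NRF2 targets 9 of 15 rose and 2 fell (camera adjusted p = 0.0035; adjusted p = 0.528 with an estimated correlation), with HMOX1 above and AKR1B10 up 2.12-fold, the second an uncertain value because of a close relative. GCLC and GCLM, the subunits of the glutathione-synthesis enzyme, had log2 fold changes of -0.16 and -0.18, directions that flipped under upper-quartile scaling (0.24 and 0.23) and the stricter filter (0.16 and 0.14), where both passed as higher. Both calls were lost with transcript length offsets (edgeR adjusted p = 0.0538 and 0.176). For GCLM the call was also lost without the third control (edgeR adjusted p = 0.097) or the second HO53 library (0.147). Of the non-epithelial markers 8 of 14 rose (camera adjusted p = 0.0158; adjusted p = 0.53 with an estimated correlation), with VWF up 25.1-fold to 27.4 ± 0.83 CPM and PECAM1 up 3.54-fold.

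Among the lists that fell at 8 h, all 27 oxidative phosphorylation genes fell under TMM scaling, and 15 fell and 9 rose under upper-quartile scaling (camera adjusted p = 7.88e-06; adjusted p = 0.56 with an estimated correlation; median -0.55, or -0.77 relative to all genes), with CYC1 down 3.06-fold and NDUFA9 down 2.44-fold. Of the replication and mitosis genes 21 of 25 fell and 1 rose (camera adjusted p = 1.21e-07; adjusted p = 0.269 with an estimated correlation), with MCM4 down 9.73-fold and TK1 up 2.41-fold. Of the deacetylase and acetyltransferase genes 20 of 26 fell and 4 rose (camera adjusted p = 6.32e-05; adjusted p = 0.433 with an estimated correlation; 20 and 5 adjusted over the list alone; median -0.66, or -0.88 relative to all genes), with EP300 down 3.51-fold, KAT7 down 2.53-fold, HDAC9 up 2.22-fold and HDAC5 up 1.45-fold. Under upper-quartile scaling 14 of these genes fell and 10 rose. Of the unfolded protein response genes 14 of 15 fell and 1 rose (camera adjusted p = 0.00582; adjusted p = 0.651 with an estimated correlation), with CRELD2 down 2.53-fold, SEL1L down 2.16-fold and HSPA5 up 1.29-fold. Under upper-quartile scaling 8 unfolded protein response genes fell and 3 rose. Of 9 heat shock genes 5 fell and 2 rose (camera adjusted p = 0.0144; adjusted p = 0.433 with an estimated correlation), with HSPH1 down 5.96-fold, HSPA8 down 2.51-fold and DNAJB1, a co-chaperone, up 2.28-fold. HSPB1 was higher by 0.17 on the log2 scale (edgeR adjusted p = 0.0077), a call lost under median-of-ratios (0.352) and total-count scaling (0.0881), without the filter (0.245) and with DESeq2 (0.316). The heat shock call was lost under upper-quartile scaling (adjusted p = 0.0931), and the stricter filter ended those of the heat shock (0.294, median -0.55), unfolded protein response (0.279, -0.23) and deacetylase lists (0.0979, -0.34) and of the non-epithelial list, whose median was larger under it (0.065, 1.09 against 0.59). In the expression-matched comparison the oxidative phosphorylation and deacetylase medians at 8 h ranked at percentiles 10.0 and 7.98.

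Of the cell type markers at 8 h, 1 of 21 ciliated markers rose and 9 fell (7 fell adjusted over the list alone; camera adjusted p = 0.491), and their median of -0.40 flipped to 0.01 under upper-quartile scaling. RFX3, a ciliogenesis factor, rose 1.42-fold, MYB and MCIDAS fell 2.82-fold and 2.05-fold, and FOXJ1 did not pass (37.3 ± 5.2 CPM with HO53 and 32.5 ± 7.4 CPM in the controls, SD, n = 3, edgeR adjusted p = 0.365). FOXJ1 at 8 h passed under upper-quartile scaling (log2 fold change 0.60, edgeR adjusted p = 0.00946) and under the stricter filter (0.52, edgeR adjusted p = 0.0261). Of the basal markers 10 of 16 rose and 3 fell (camera adjusted p = 0.116), with KRT14 up 8.35-fold and NGFR up 3.15-fold (27.1% of its exonic bases overlap other genes). DLK2 fell 2.52-fold. CAV1 was 1.13-fold lower, which flipped under upper-quartile scaling (log2 fold change 0.23) and the stricter filter (0.14). KRT5 did not pass at 8 h (log2 fold change 0.01 ± 0.07 (SE), edgeR adjusted p = 0.869), with a sign that flipped under median-of-ratios (-0.09) and total-count scaling (-0.07) and a value of 0.42 that passed under upper-quartile scaling (edgeR adjusted p = 1.45e-06). It also passed under the stricter filter (0.33, edgeR adjusted p = 3.71e-05). The basal list itself passed camera at 8 h under upper-quartile scaling (0.00766). Of the club and goblet cell markers 7 of 16 rose and 2 fell (camera adjusted p = 0.692), with AGR2 up 1.64-fold, FCGBP up 2.55-fold and CYP2F1 down 2.18-fold. MUC5AC rose 1.26-fold (edgeR adjusted p = 0.015), a call lost under median-of-ratios (0.0831) and total-count scaling (0.0739), with DESeq2 (0.134), and without the first (0.0531) or second control (0.0656) or the second HO53 library (0.163). Of the ionocyte, neuroendocrine and tuft cell markers 7 of 10 rose and 1 fell (camera adjusted p = 0.215), with POU2F3 up 4.14-fold, ATP6V0D2 up by 1.58 on the log2 scale and LRMP down 2.14-fold. Of the junction genes 11 of 19 rose and 6 fell (camera adjusted p = 0.216), with CLDN3 up 3.47-fold, CLDN4 up 2.37-fold, MARVELD3 down 1.80-fold and MARVELD2 down 1.70-fold.

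After 24 h, 23 of 25 genes of DNA replication and mitosis were lower in the treated cells, a list call lost with an estimated correlation (adjusted p = 0.114 with an estimated correlation), and all 14 neuronal genes were higher. TOP2A, the topoisomerase of dividing cells, fell 25.7-fold from 31.7 ± 2.1 CPM to 1.23 ± 0.16 CPM (SD, n = 3; log2 fold change -4.68 ± 0.14 (SE), edgeR adjusted p = 9.19e-17), and CCNB1, cyclin B1, fell 50.3-fold. SYT11, a synaptotagmin, rose 246-fold from 0.739 ± 0.12 CPM to 183 ± 19 CPM (SD, n = 3). S100A9, a subunit of calprotectin, rose 5.51-fold to 2870 ± 150 CPM. Ciliated, club and goblet cell markers were called lower as lists, but not with an estimated correlation (adjusted p = 0.85 and 0.788 with an estimated correlation), and 4 of 16 club and goblet markers rose. FOXJ1 fell 2.84-fold, from 22.3 ± 5.4 CPM to 7.84 ± 0.79 CPM, and CYP2F1, a club cell cytochrome P450, fell 15.1-fold.

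The edgeR test called 19843 genes at 24 h, 10449 higher and 9394 lower, of which 6193 were at least 2-fold higher and 2866 at least 2-fold lower, and upper-quartile scaling gave 14051 higher and 6772 lower. Among the genes named by the rule with a mean CPM of at least 5 over all 18 libraries, which leaves out CCNB1, the largest rises were in INA (261-fold), PADI3 (258-fold), SYT11, CEND1 (136-fold), the metabolic transcription factor MLXIPL (101-fold) and TMEM59L (79.6-fold). By the same rule the largest falls were in the mitotic motor CENPE (103-fold), the kinetochore protein ZWINT (81.9-fold), SMC2 (61.6-fold), the cell cycle transcription factor E2F3 (35.5-fold), the alcohol dehydrogenase ADH7 (29.5-fold) and TOP2A.

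Of 25 replication and mitosis genes 23 fell and 1 rose at 24 h, with a median log2 fold change of -3.53 (limma camera adjusted p = 9.19e-17; adjusted p = 0.114 with an estimated correlation). MCM6 fell 25.5-fold and TK1 rose 1.26-fold. All 14 neuronal genes rose, with a median of 4.27 (camera adjusted p = 1.42e-11; adjusted p = 0.00053 with an estimated correlation), the one list call at any time that also held with an estimated correlation. STMN3, a neuronal stathmin, rose 13.6-fold and TUBB3 rose 7.45-fold. Of the deacetylase inhibitor list 13 of 16 rose and 1 fell (camera adjusted p = 4.06e-06; adjusted p = 0.269 with an estimated correlation; 13 and 2 adjusted over the list alone), with CLU up 10.2-fold and CDKN1A up 3.07-fold. H1F0 was 2.49-fold higher. The fall of CDKN1C (1.46-fold) was lost under upper-quartile scaling (edgeR adjusted p = 0.138), under the stricter filter (0.132) and without the second HO53 library (0.0514). Of the antimicrobial genes 12 of 18 rose and 2 fell (camera adjusted p = 0.00154; adjusted p = 0.433 with an estimated correlation), with DEFB1 up 7.18-fold and BPIFB1 down 1.77-fold. ADM was 1.30-fold lower, a call lost under upper-quartile scaling (edgeR adjusted p = 0.172) and the stricter filter (0.114). CAMP had 0 counts in the controls and between 11 and 18 per HO53 library, at least 4.36-fold higher when the controls are set at 3 counts per library. All 6 metallothioneins rose (camera adjusted p = 0.0322; adjusted p = 0.433 with an estimated correlation), with MT1F up 3.21-fold and MT1E up 2.35-fold. Intervals and floors on such counts cover counting error only.

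Of 21 ciliated cell markers 14 fell and 0 rose at 24 h (camera adjusted p = 0.0456; adjusted p = 0.85 with an estimated correlation), with DNAH5, an axonemal dynein, down 3.94-fold and MCIDAS down 3.53-fold. Of 16 club and goblet cell markers 10 fell and 4 rose (camera adjusted p = 0.0484; adjusted p = 0.788 with an estimated correlation). MUC5AC fell 2.68-fold from 287 ± 47 CPM to 107 ± 5.7 CPM (SD, n = 3; edgeR adjusted p = 9.16e-10), CREB3L1 fell 2.58-fold, and MUC5B and FCGBP rose 1.71-fold and 2.85-fold. This call was lost under total-count scaling (camera adjusted p = 0.0514) and without replicate 2 (0.0525), and the stricter filter ended it (0.294, median -0.31) and that of the ciliated list (0.254, median -0.48). Of the 15 genes of the unfolded protein response list 11 fell and 2 rose (camera adjusted p = 0.00872; adjusted p = 0.675 with an estimated correlation), with DNAJB9 and XBP1 down 3.23-fold and 2.87-fold and PDIA4 up 1.35-fold. HSPA5 rose 1.17-fold, a call lost under median-of-ratios scaling (edgeR adjusted p = 0.0546) and without the first (0.0952) or second control (0.0527) or the first HO53 library (0.101). Of 27 oxidative phosphorylation genes 20 fell and 3 rose (camera adjusted p = 0.00486; adjusted p = 0.805 with an estimated correlation; median -0.52, or -0.66 relative to all genes), with ATP5MC1 down 2.74-fold, NDUFA9 down 1.86-fold, NDUFA2 up 1.33-fold and SDHB up 1.18-fold. Of 26 deacetylases and acetyltransferases 20 fell and 4 rose (camera adjusted p = 0.000794; adjusted p = 0.498 with an estimated correlation), with EP300 down 2.64-fold, KAT6B down 2.24-fold, HDAC3 up 1.58-fold and KAT6A up by 0.33 on the log2 scale. Of 9 heat shock genes 6 fell and 1 rose (camera adjusted p = 0.0358; adjusted p = 0.498 with an estimated correlation), with HSPH1 down 6.54-fold, HSPA8 down 1.61-fold and DNAJB1 up 1.55-fold. The counts of these lists were the same adjusted over the list alone. Under upper-quartile scaling 17 oxidative phosphorylation genes fell and 8 rose, 15 deacetylases and acetyltransferases fell and 7 rose, and 8 unfolded protein response genes fell and 3 rose. The oxidative phosphorylation and heat shock calls were lost under upper-quartile scaling (0.0643 and 0.121), the heat shock call under total-count scaling (0.0677), and the stricter filter ended the oxidative phosphorylation (0.393, median -0.24), heat shock (0.393, -0.13), unfolded protein response (0.267, -0.19) and deacetylase calls (0.228, -0.28).

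Of the other cell type markers at 24 h, 5 of 16 basal markers rose and 7 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.491), and their median of -0.10 flipped under upper-quartile (0.18) and total-count scaling (0.05). BCAM and NGFR, the second uncertain by its overlap, rose 2.97-fold and 3.14-fold, and DLK2 and CAV1 fell 5.52-fold and 3.20-fold. KRT5 did not pass (log2 fold change -0.02 ± 0.07 (SE), edgeR adjusted p = 0.776), and its sign flipped under upper-quartile scaling (0.26, edgeR adjusted p = 0.000364), the stricter filter (0.25) and total-count scaling (0.13). Of the squamous genes 8 of 16 rose and 6 fell (camera adjusted p = 0.371), with KRT6B, again uncertain, up 26.0-fold and CNFN up 5.14-fold but TGM1 and IVL down 2.08-fold and 1.82-fold. Of the ionocyte, neuroendocrine and tuft cell markers 6 of 10 rose and 4 fell (camera adjusted p = 0.405), a list whose median of 0.57 was positive while camera's direction was down. FOXI1, an ionocyte factor, was down 5.99-fold and LRMP 12.3-fold, and POU2F3 and ATP6V0D2 were up 1.69-fold and 2.78-fold. Of the junction genes 5 of 19 rose and 9 fell (camera adjusted p = 0.491), with CDH1, E-cadherin, up 1.65-fold, CLDN3 up 2.17-fold, CLDN7 down 2.20-fold and MARVELD2 down 1.82-fold. The median of this list, -0.15, flipped to 0.13 under upper-quartile scaling. Of the non-epithelial markers 6 of 14 rose and 4 fell (camera adjusted p = 0.354).

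**Figure D3:**
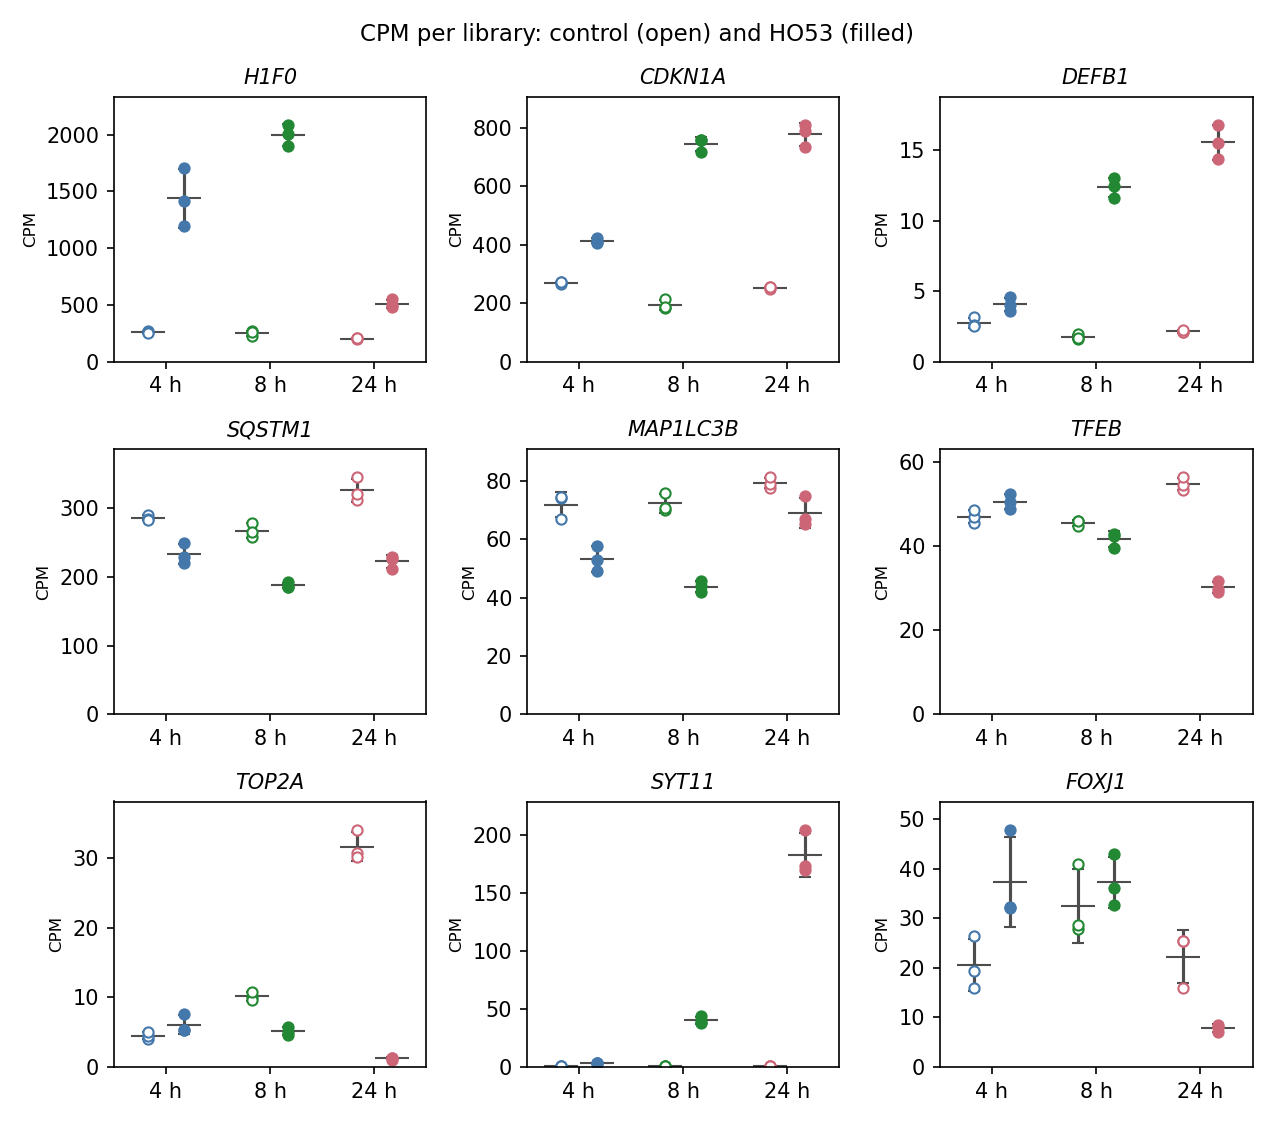
CPM per library (y axes, from 0) at 4 h, 8 h and 24 h (x axes) for 9 genes, with open circles for the 3 control libraries, filled circles for the 3 HO53 libraries and dashes with bars for the mean and SD. H1F0 has its highest mean with HO53 at 8 h, TOP2A falls to 1.23 CPM and SYT11 rises to 183 CPM at 24 h, and the small differences in MAP1LC3B at 24 h, SQSTM1 at 4 h and TFEB at 8 h change direction under upper-quartile scaling.

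The remaining lists did not pass limma's camera test at any time under TMM scaling. Targets of p53 had 6 of 17 genes higher and 6 lower at 4 h, 9 and 7 at 8 h and 5 and 12 at 24 h (adjusted p = 0.757, 0.708 and 0.491). Of 20 NF-kB targets and cytokines 8, 14 and 13 rose and 4, 3 and 4 fell (0.354, 0.275 and 0.355), with medians of 0.54, 1.53 and 1.19. Of 20 interferon-stimulated genes 8 fell at 4 h (3 adjusted over the list alone), 5 rose at 8 h (4 adjusted over the list alone) and 13 fell at 24 h (12 adjusted over the list alone), with camera adjusted p of 0.371, 0.491 and 0.262. Of 15 ATF4 targets 6, 7 and 6 rose and 8, 4 and 5 fell (0.572, 0.144 and 0.172). Of 21 cholesterol synthesis genes 7, 6 and 13 rose and 11, 12 and 5 fell (0.082, 0.0549 and 0.23), with medians of -0.22 at 4 h and -0.39 at 8 h that flipped to 0.09 and 0.01 under upper-quartile scaling. Of 30 ribosomal protein genes 23, 16 and 1 rose and 0, 1 and 20 fell (0.0712, 0.262 and 0.144; 24 rose at 4 h adjusted over the list alone), and the median at 24 h, -0.25, flipped to 0.04 under upper-quartile scaling. Of 13 protein genes of the mitochondrial genome 1, 10 and 0 rose and 1, 0 and 13 fell (0.878, 0.23 and 0.232; 0 and 1 at 4 h adjusted over the list alone), the last a fall with a median of -0.29 that was 0.00 under upper-quartile scaling. Of 15 fatty acid oxidation genes 6, 5 and 5 rose and 5, 7 and 9 fell (0.295, 0.524 and 0.661), with 7 and 7 at 8 h adjusted over the list alone. Of 7 aryl hydrocarbon receptor targets 3, 4 and 5 rose and 0, 1 and 2 fell (0.216, 0.217 and 0.43). Other lists were called at some times and not at others. Glycolysis genes were not called at 8 h (8 rose and 8 fell, 0.491) or 24 h (8 and 9, 0.524). Clock genes were not called at 8 h (7 and 8, or 8 and 8 adjusted over the list alone, 0.23) or 24 h (5 and 6, 0.757). NRF2 targets (6 and 7, 0.306), membrane-bound mucins (3 and 4, 0.666), immediate early genes (9 and 3, 0.142) and mesenchymal genes (9 and 2, 0.0607) were not called at 24 h. Heat shock genes were not called at 4 h (3 and 5, 0.194). The median and the mean differed in sign for ATF4 targets at 4 h (-0.28 and 0.07), p53 targets at 4 h (0.03 and -0.04), glycolysis at 8 h (-0.03 and 0.18), and fatty acid oxidation at 8 h (-0.12 and 0.39). At 24 h they differed for NRF2 targets (-0.13 and 0.23), clock genes (-0.04 and 0.17) and junction genes (-0.15 and 0.02). Upper-quartile scaling turned to positive the medians of ATF4 targets at 4 h (0.03), glycolysis (0.37), fatty acid oxidation (0.29) and clock genes (0.20) at 8 h. It did the same at 24 h for NRF2 targets (0.16), p53 targets (0.03) and clock genes (0.24), and total-count scaling for NRF2 targets (0.02) and clock genes (0.11). Median-of-ratios scaling turned to negative the medians of p53 targets at 4 h (-0.01) and of ATF4 targets (-0.02) and glycolysis (-0.03) at 24 h. Under upper-quartile scaling camera also called ribosomal protein genes at 4 h (9.93e-05) and 8 h (0.00445), and junction genes at 4 h (0.00553) and 8 h (0.00415). It called glycolysis (0.0382), ATF4 targets (0.0486) and mitochondrial genes (0.0368) at 8 h. It called fatty acid oxidation (0.0486) and metallothioneins (0.0373) at 4 h, and cholesterol synthesis (0.0474), immediate early (0.0474) and mesenchymal genes (0.0283) at 24 h. Total-count scaling called the mesenchymal genes at 24 h as well (0.035). Cholesterol synthesis was called at 8 h under median-of-ratios (0.0318) and total-count scaling (0.0355).

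The medians of all lists were also ranked among 10000 random lists matched on expression, a comparison that takes no account of correlation between members. Of the lists not called by camera, NF-kB targets ranked at percentiles 99.98, 100 and 100 at the 3 times and interferon-stimulated genes at 0, 99.99 and 0. Also outside the central 95% were heat shock (0.11), mitochondrially encoded (0.08), ciliated (99.86), neuronal (99.26), metallothionein (98.44) and junction genes (98.33) at 4 h, and junction (99.73) and basal genes (99.23) at 8 h. At 24 h these were cholesterol synthesis (99.99), immediate early (99.92), squamous (99.25), mesenchymal (99.03) and aryl hydrocarbon receptor target genes (98.11). Of the lists called by camera, those inside the central 95% and not ranked above were glycolysis (89.64) and the deacetylases and acetyltransferases (3.61) at 4 h, and non-epithelial markers (91.88) and the unfolded protein response (3.16) at 8 h. At 24 h they were club and goblet markers (7.52), deacetylases and acetyltransferases (8.27), oxidative phosphorylation (9.67), heat shock (10.2) and the unfolded protein response (17.98).

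**Figure D4:**
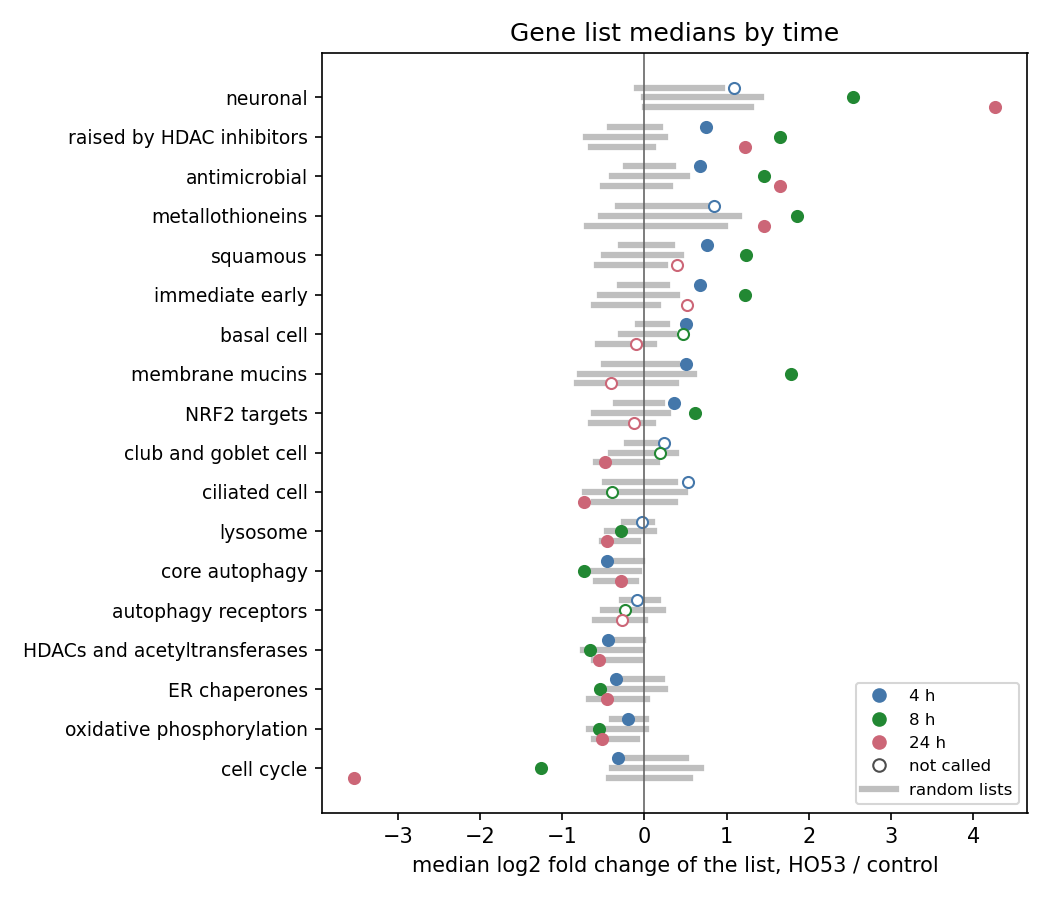
Median log2 fold change of HO53 over control (x axis) for 18 gene lists (y axis) under TMM scaling, coloured by time, with filled points where limma's camera test was passed, open points where it was not, and grey bars that hold the central 95% of medians of 10000 random lists matched on expression. The neuronal list rises to 4.27 and the cell cycle list falls to -3.53 at 24 h, while the core autophagy median at 24 h is 0.00 and the lysosome median at 8 h is 0.12 under upper-quartile scaling.

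The effect of HO53 also differed between times in many genes, as tested by the interaction itself. TOP2A was 0.45 higher on the log2 scale at 4 h and fell by 4.68 at 24 h, a difference of -5.13 ± 0.19 (SE, edgeR adjusted p = 1.2e-14) that is set against controls rising from 4.47 ± 0.49 CPM to 31.7 ± 2.1 CPM between these times. MCM6 fell by 1.82 at 4 h and by 4.91 at 8 h, a difference of -3.09 ± 0.11. In the other direction MLXIPL rose by 0.62 at 4 h and by 6.66 at 24 h, a difference of 6.04 ± 0.18 (SE, edgeR adjusted p = 9.91e-16). Between 4 h and 8 h the effect differed in 10531 genes, 4654 with a higher and 5877 with a lower later value (5972 and 4732 under upper-quartile scaling). Between 4 h and 24 h it differed in 14604 genes, 7083 and 7521 (9492 and 5759 under total-count scaling). Between 8 h and 24 h it differed in 13561, 6905 and 6656. That last split was 9479 and 4677 under total-count scaling and the other way under upper-quartile scaling (5711 and 8031).

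Many genes kept one direction. H1F0, CDKN1A, DEFB1, HMOX1, INA and RETREG1 were called higher at all 3 times, and EP300, MCM6, CYP2F1 and TAX1BP1 were called lower. In all, 10555 genes were called in the same direction at all 3 times, 5121 higher and 5434 lower (8687 and 2800 under upper-quartile scaling), where independent lists of these sizes would share 1398 and 828. The 3 comparisons used separate controls. Another 2924 genes were called in opposite directions at different times, such as IVL and TGM1.

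As a background, the untreated cultures were compared between 24 h and 4 h. TOP2A was higher in the 24 h controls by 2.82 ± 0.12 on the log2 scale (SE, edgeR adjusted p = 4.96e-12). In all, 7471 genes differed (4573 higher and 2898 lower at 24 h by edgeR), 326 of them at least 2-fold higher and 359 at least 2-fold lower. Under total-count scaling the split was 3241 higher and 4644 lower. At least 2-fold differences were thus counted in 685 genes between control times and in 5257, 9972 and 9059 genes with HO53 at 4 h, 8 h and 24 h.

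Coordinates on GRCh38, from GENCODE 29, place the genes reported at every time as follows. H1F0 (ENSG00000189060) lies on chromosome 22 from 37805093 to 37807436, CDKN1A (ENSG00000124762) on chromosome 6 from 36676460 to 36687339, and DEFB1 (ENSG00000164825) on chromosome 8 from 6870575 to 6878022. CAMP (ENSG00000164047) lies on chromosome 3 from 48223347 to 48225491 and TFEB (ENSG00000112561) on chromosome 6 from 41683978 to 41736259. MAP1LC3B (ENSG00000140941) lies on chromosome 16 from 87383995 to 87404779, SQSTM1 (ENSG00000161011) on chromosome 5 from 179806398 to 179838078 and ULK1 (ENSG00000177169) on chromosome 12 from 131894651 to 131923167. FOXJ1 (ENSG00000129654) lies on chromosome 17 from 76136333 to 76141299, MUC5AC (ENSG00000215182) on chromosome 11 from 1157953 to 1201138 and KRT5 (ENSG00000186081) on chromosome 12 from 52514575 to 52520687. The values are sums over all transcripts of each gene, so they belong to whole genes and not to single exons.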

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

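Camera on the difference between 24 h and 4 h was chosen after the results were seen, as was total-count scaling. The effect of HO53 differed between 4 h and 8 h in 10531 genes, between 4 h and 24 h in 14604 and between 8 h and 24 h in 13561, by edgeR's interaction test.

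From 4 h to 8 h the largest differences in log2 fold change among named genes were 3.73 for PADI3, 3.47 for CLCNKA and 3.37 for CEND1, against -3.09 for MCM6, -2.56 for SMC2 and -2.55 for MCM5. From 4 h to 24 h they were 6.04 for MLXIPL, 5.50 for SYT11 and 5.41 for TMEM59L, against -5.22 for ZWINT, -5.13 for TOP2A and -4.81 for CENPE. From 8 h to 24 h they were 3.34 for TMEM59L, 3.12 for SEMA6B and 3.11 for L1CAM, against -4.25 for CENPE, -4.15 ± 0.92 (SE) for FLOT1, an uncertain gene with copies on alternative haplotypes, and -4.06 ± 0.76 (SE) for CXCL11.

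Of 35 lists, limma's camera called 12 for the difference between 24 h and 4 h. Their median differences were -2.95 for cell cycle, 3.46 for neuronal genes, -0.59 for basal, -1.27 for ciliated, -0.43 for ribosomal proteins, 0.44 for cholesterol synthesis, -0.65 for club and goblet, 0.81 for clock, -0.70 for membrane-bound mucins, -0.12 for lysosome, 0.38 for genes raised by deacetylase inhibitors and -0.36 for rare airway cells. With an estimated correlation 1 call held, that of the neuronal genes (adjusted p = 0.0125 with an estimated correlation). Under total-count scaling the lysosome list was not called.

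Among the unmatched transcripts, left out of every comparison, 782 of 7244 tested were higher with HO53 at 4 h, 1233 at 8 h and 1166 at 24 h, and 1014, 1626 and 1660 were lower.

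Core autophagy genes were lower at 4 h and 8 h. None of the 4 scalings tried removed the fall at 8 h, and the median was -0.34 under the one that raised it most. All 4 rest on the same counts, so a shift common to them cannot be excluded. Genes at a similar expression level also fell at 8 h, with a median of -0.38 for matched random lists. The list fell further, to -0.74 at percentile 0.83, which argues against expression level as the only cause. That ranking takes no account of correlation between members. At 24 h the percentile was 72.5 and the upper-quartile median 0.00, but camera called no difference from 4 h (adjusted p = 0.446). An effect of HO53 on these genes at 8 h is a hypothesis found on the same data, and the call did not hold with an estimated correlation.

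More genes were detected with HO53. A depth difference was argued against by thinning all libraries to one total, after which the lowest HO53 library at 24 h still exceeded the highest control by 2618 genes (988 at 4 h and 1993 at 8 h). Genomic DNA was argued against because 5 of 231 silent olfactory receptor genes (2.2%) were detected with HO53 at 24 h and 303 of 1544 other silent protein-coding genes (19.6%), a ratio of 0.11. Broader transcription under HO53 may remain as a hypothesis, with other technical causes not tested.

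Ciliated cell markers were lower at 24 h, a call lost with an estimated correlation (adjusted p = 0.85 with an estimated correlation). An equal loss of ciliated cells as the only cause was argued against by the spread of the markers, with an interquartile range of 0.96 and 95% intervals above the median fall for 7 markers and below it for 6. A spread in ciliation between inserts cannot be told from an effect of HO53. In mean log2 CPM the lowest of 9 controls lay 0.02 above the highest HO53 library at 24 h, less than the SD of 0.14. That control was of 4 h (2.09), when the groups met at 2.73. The 4 h rise and the difference from 4 h to 24 h share this limit. At 24 h controls stood at 2.48, 2.97 and 2.96 and HO53 libraries at 2.06, 2.01 and 1.79, further apart.

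For 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. The real split gave 16841, 20090 and 19843 genes at the 3 times, where the highest other split gave 0, and 7471 genes in the controls, where the highest other gave 1, with 1 split as large as the real one in each case, itself. Of 60 splits within each time the first was the real one and the others were drawn. Only the real one gave as many genes in the same direction at all times (10555, highest other 0). It was also the only one for 8 h against 24 h (13561, highest other 13071). For 4 h against 8 h (10531, highest other 16300) and 4 h against 24 h (14604, highest other 16164), 2 gave as many, the real one included. The higher draws turned over all labels of one time and kept another, a structure that adds the effects of 2 times, while the 40 draws with mixed labels at all times called 0 genes. Mixed labels place the difference between treatments, or between times in the controls, inside the groups and so raise the spread. A count near 0 follows from that, so these splits do not measure chance. For list calls 2 splits, the real one included, reached 47 (highest other 47), and the other draws gave between 21 and 47 with a median of 37. The real number thus stood little above these draws. With 3 libraries of each treatment no regrouping splits them evenly, so every draw keeps part of the HO53 difference. These draws therefore cannot tell how many lists would be called without treatment.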

How the results depend on the processing

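Total-count scaling and the list tests under other scalings and the stricter filter were chosen after the data were seen. Over all alternatives, 5163 values of named genes kept direction and side of the threshold, 63 lost the call, 7 gained it and 31 reversed, and 427 list values were kept and 88 lost. Causes were not tested unless a sentence says so.

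The stricter filter, which tests fewer genes (12856), called 10625 genes at 4 h (8745 shared), 11459 at 8 h (10204 shared), 11043 at 24 h (9627 shared) and 6481 in one direction at all times. It called 24 lists. With the usual filter, camera with an estimated correlation called 1 list and fry 92. Leaving out 1 library gave 15523 to 16134 genes at 4 h, 19189 to 19835 at 8 h, 18616 to 19664 at 24 h, 9713 to 10212, 13793 to 14464 and 12921 to 13358 for the 3 differences between times, 5947 to 7411 in the controls, and 10001 to 10517 at all times. Leaving out a replicate number in all groups gave 47 to 53 lists.

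Same-numbered libraries of the 2 treatments correlated between -0.06 and 0.07 in their deviations from the group means. At 8 h each control matched best with the HO53 library of its number (0.07, 0.03 and 0.04), which was not so for all at 4 h and 24 h. Values this weak give little sign of pairing by number but cannot exclude it. With the replicate block, 16929, 20154 and 19850 genes were called at the 3 times and 10571 at all times, and with the replicate block within each time 16571, 19875, 19530 and 10323.

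Reversed values (log2) were as follows. For KRT5 at 8 h they were -0.093 with median-of-ratios factors and with DESeq2, -0.066 with total counts, -0.072 without a filter, and -0.031 with only the times compared. Without 1 library KRT5 at 8 h ranged from -0.041 to 0.09, with 4 of 6 fits reversed, and KRT5 at 24 h from -0.095 to 0.024, with 1 of 6 reversed. Upper-quartile factors gave PFKL 0.024, ADM 0.113 and SQSTM1 0.01 at 4 h, GCLC 0.244, GCLM 0.227, CAV1 0.233, TFEB 0.278 and ULK1 0.08 at 8 h, and MAP1LC3B 0.085, ULK1 0.181 and KRT5 0.262 at 24 h. Total counts gave ULK1 0.046 and KRT5 0.128 at 24 h. The stricter filter gave ADM 0.021 at 4 h, GCLC 0.156, GCLM 0.139, CAV1 0.145 and TFEB 0.19 at 8 h, and MAP1LC3B 0.074, ULK1 0.17 and KRT5 0.251 at 24 h. Depth limits CAMP, whose counts at 4 h and 8 h lay near the floor.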

Other observations

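The comparison of zinc finger genes was chosen after their values were seen. Of 489 tested genes with ZNF symbols, many of which encode DNA-binding repressors, 370 fell at 4 h, 381 at 8 h and 352 at 24 h, and 46, 50 and 68 rose. Their medians were -0.61, -0.79 and -0.56, against -0.02, -0.04 and -0.10 for 16505 other protein-coding genes. Under upper-quartile scaling the medians were -0.30, -0.39 and -0.28, and those of the other genes flipped to 0.28, 0.36 and 0.18. The members are similar in sequence, so their counts are uncertain.

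More noncoding genes rose than fell, but class cannot be told apart from expression level, which was not matched. Of 7534 long noncoding RNA genes, 40.6%, 50.6% and 43.5% rose at 4 h, 8 h and 24 h and 6.9%, 9.9% and 13.3% fell. Of 16994 protein-coding genes, 30.3%, 37.1% and 35.3% rose and 40.7%, 45% and 47.1% fell. Of 2564 pseudogenes, 30%, 39% and 38.4% rose and 10.6%, 13.6% and 13.4% fell.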
